A study of Homo sapiens with 12 samples.

How the data were processed

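RNA from MDA-MB-231 cells was measured on 12 single-channel arrays. MDA-MB-231 is an established human breast cancer line whose parent cells lack estrogen receptor alpha (ERα). Per the labels, the cells stably expressed wild-type ERα (WT) or a mutant ERα called LQ. The sources used here do not spell out the code LQ, so it is left as it stands. Cells of each line were controls or received 10 nM E2 (estradiol) for 1 or 2 h. Each of the 6 groups had 2 arrays, named A and B in the labels. Nothing in the labels says whether A and B were separate cultures, so p-values measure the spread between these samples, which may be technical.

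The deposited values are linear intensities, 1 per probe set and array, with probe set names of the Affymetrix type. The software that summarized the probes and the normalization it applied are not given in the sources used here. The deposited intensities of every array had nearly the same mean after 2% of the values was trimmed at each end, between 148.2 and 148.9, so a scaling step preceded deposit. Medians of the deposited intensities lay between 34.2 and 48.3. Detection calls were not used here. Of 22283 probe sets, 68 control probe sets were kept out of the tests, which left 22215. The platform's gene table gave 19065 of these a single gene symbol, 1043 several and 2107 none. Through gene identifiers, 19059 of the single-gene probe sets matched the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. Genes are named only from probe sets with a single symbol.

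A rule written before the data were examined kept the deposited scale if the array medians of log2(intensity + 16) lay within 0.2 of each other. They spanned 0.36, so the intensities were quantile normalized and then transformed to log2(normalized intensity + 16). The pseudocount makes a fold change understate the change of dim genes. The third of probe sets with the lowest mean over all arrays (7405) was left out, and 14810 were tested. These held 13066 single-gene probe sets for 8785 genes. Probe sets whose names end in _x_at or _s_at can pick up related transcripts of a family.

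Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, which left 6 residual degrees of freedom plus 8.09 from the prior. The moderated test used an intensity trend (eBayes with trend), was two-sided, and was adjusted by Benjamini-Hochberg within each of 8 contrasts, with 0.05 as the threshold. The contrasts were 1 and 2 h of E2 against control within WT and within LQ, the difference between the lines in the E2 effect at each time (interaction), and LQ against WT in the controls and averaged over control, 1 h and 2 h. Errors after ± are SDs over the arrays of a group, and SE is the standard error of a fitted log2 difference. The number of arrays limits the precision.

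Before the data were examined, 18 gene lists with 486 genes in all were fixed. They covered classical estrogen-induced and estrogen-repressed genes, immediate early genes, MAPK feedback and ETS genes, NF-kB targets and cytokines, cell cycle, TGF-beta targets, epithelial and luminal genes, mesenchymal genes, proteases and inhibitors, p53 targets, cholesterol and fatty acid synthesis, unfolded protein and amino acid stress, heat shock, interferon response, hypoxia and glycolysis, estrogen receptor coregulators, and markers of other cell types. On the array were 436 of these genes, and 359 passed the filter. Each gene was represented by its probe set with the highest mean. A list was tested with camera (preset correlation 0.01), adjusted over all 144 list and contrast pairs, and again with an estimated correlation and with fry. Members were counted both as adjusted over all probe sets and as adjusted over the list alone.

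Named genes followed a rule fixed at the same time. For each contrast it takes up to 12 of the highest and 12 of the lowest log2 differences among single-gene probe sets past the threshold whose arrays do not overlap between the sides. Where fewer than 10 probe sets passed, up to 8 more per direction at an unadjusted p under 0.01 are named as not passing. From each list it takes 2 to 4 members, and always ESR1, PGR, TFF1, GREB1, MYC, CCND1 and CTSD.

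The letters A and B come from the labels and run through all groups. The deviations of the A arrays from their group means were correlated in each of the 15 pairs of groups, with r from 0.13 to 0.40 and a median of 0.22, all above 0.1. The letters were therefore treated as pairing the arrays. The main analysis has no letter term, and the count with the letter as a block is given beside it where it differs by more than 1.5 times or changes a call. In every contrast the block raised the number of probe sets with an unadjusted p under 0.05. At 2 h in WT it went from 533 to 969, and at 1 h in LQ from 284 to 518, where chance gives 740. Letter differences left in the residual lower the main counts, so a main count below chance does not show that E2 had no effect. The second principal component (21.6% of the variance) separated the letters and the first (29.1%) the lines, each with an exact permutation p of 0.0022, the smallest that 924 splits can give. Hybridization control spike-ins averaged 1015 ± 116 on the A arrays and 782 ± 124 on the B arrays (exact permutation p = 0.013, n = 6 each).

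Alternatives tried were the deposited scale, a shift of each array to a common median, pseudocounts of 1 and 64, no filter on dim probe sets or a stricter one, no trend, a robust prior, the letter as a block, only the compared groups, 1 probe set per gene, a threshold of 0.10, the other list tests, a rank correlation, and each array left out in turn. Where leaving out an array left a single one in a group, that array was assumed to vary like those of the other groups. The procedure was tested on simulated data for the 14810 probe sets. For 1 h of E2 in WT it recovered 9.55% of simulated 1.5-fold changes, 41.2% of 2-fold and 88.5% of 3-fold changes. For LQ against WT over all times it recovered 46.9%, 91.9% and 100% in the same order. False calls made up 5.71% and 4.90% of the calls. A list shifted by 0.5 log2 was called in 20 of 20 draws, and 3 of 340 tests of unshifted lists were called too. These list rates hold for the simulated noise only. In the data, 2 of 22 list calls also passed with an estimated correlation, so the draws do not show how reliable the list calls are there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.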

Results

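Transcript levels were measured on 12 arrays of MDA-MB-231 breast cancer cells that stably expressed WT ERα or the mutant LQ. For each receptor there were 2 control arrays, 2 after 1 h and 2 after 2 h of 10 nM E2, the natural ligand of the receptor. Levels are given as normalized intensities. The design asks which transcripts respond to E2 within 1 or 2 h through either receptor, whether the response differs between the receptors, and how the lines differ without regard to E2. The comparisons of E2 with control have 2 arrays on each side, and their number limits the precision.

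ESR1, the gene of ERα, was expressed at a high level in both lines. Its brightest probe set read 2164 ± 369 in WT and 1802 ± 274 in LQ (SD, n = 6 each), a log2 difference of -0.26 (SE 0.07, adjusted p = 0.0309, 1.20-fold higher in WT). Another bright probe set read 2081 ± 263 in WT and 1359 ± 193 in LQ (1.53-fold higher in WT, adjusted p = 7.36e-05). A further bright one read 1933 ± 424 in WT and 1179 ± 249 in LQ (1.62-fold higher in WT, adjusted p = 0.000213). The remaining bright one did not pass (log2 difference -0.18, adjusted p = 0.169). Nor did a weaker one at 189.5 ± 36.7 in WT and 143.6 ± 36.1 in LQ (-0.38, adjusted p = 0.119). A dim probe set read only 26.0 ± 9.75 and 32.9 ± 11.6 in the same order. The call of the brightest probe set held only without WT 1 h B (adjusted p = 0.00974) or without LQ 2 h A (adjusted p = 0.0177). Leaving out any of the other 10 arrays ended it, with adjusted p up to 0.0877, as did the deposited scale (0.0824), no filter (0.0634) and no intensity trend (0.154). After 2 h of E2 the ESR1 log2 change was -0.50 in WT (adjusted p = 0.423) and -0.46 in LQ (adjusted p = 1).

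In WT cells, 3 of 14810 probe sets passed the threshold after 1 h of E2. SMOX, which encodes spermine oxidase, rose 2.45-fold from 157 ± 17.5 to 409 ± 46.1 (n = 2 each, log2 change 1.29, SE 0.19). BHLHE40, a helix-loop-helix transcriptional repressor, rose 2.26-fold from 357 ± 9.46 to 830 ± 125 (log2 change 1.18, SE 0.17). KLF6, a zinc finger transcription factor of the immediate early list, was 2.85-fold lower, at 124 ± 23.3 against 381 ± 1.63 (log2 change -1.51, SE 0.21). All 3 had an adjusted p of 0.0321 and moved the same way on both letters. A further KLF6 probe set had a log2 change of -1.21 that did not pass (adjusted p = 0.734), and another, dim one differed by 0.26 in the other direction.

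No other gene passed at 1 h in WT. Genes with an unadjusted p under 0.01 and no overlap are named here as not passing. Among them were DEPP1 (log2 change 1.72, adjusted p = 0.441) and ZFP36, which encodes an mRNA-destabilizing protein (1.57, adjusted p = 0.714). Lower were MICALL1 (-1.54, adjusted p = 0.53) and JUN, a subunit of the AP-1 transcription factor (-1.30, adjusted p = 0.0731). IGLL5, RUNDC3A, MXD1, PXN, ASAP3 and HDAC5 were higher and NRG1, ATM, SULT1A1, SSPN, WASL and CXCL2 lower without passing. With the letter as a block 8 probe sets passed, which added JUN, 2 probe sets of GADD45B, CEBPB (log2 change 0.82) and OTUB2 (1.05). The 3 calls were lost, with adjusted p up to 0.532, without either WT control array, WT 1 h A, or either array of WT 2 h, LQ 1 h or LQ 2 h. They were also lost with a common median, no filter, no intensity trend or the compared groups only (adjusted p up to 0.884). Without WT 1 h B, 295 probe sets passed, 35 higher and 260 lower.

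Among the immediate early genes, which respond to many signals without new protein synthesis, 1 of 30 measured members fell at 1 h in WT and 29 did not pass. Adjusted over the list alone 4 rose, among them GADD45B (0.99) and DUSP1 (0.97), and 2 fell, KLF6 and MYC (-0.74), while the list did not pass (camera adjusted p = 0.747). The list of MAPK feedback and ETS genes shifted down (camera adjusted p = 0.0376, median log2 change -0.13, letter A -0.27, letter B 0.03, 19 measured), and adjusted p = 0.334 with an estimated correlation. None of its members passed in limma, where 767 of all probe sets had an unadjusted p under 0.05 and chance gives 740. With the letter as a block 1615 had such a p. DUSP6, a phosphatase of ERK, had a log2 change of -0.47 and SPRY2, an inhibitor of receptor tyrosine kinase signaling, one of -0.59. This list's call was lost without either WT control, either WT 1 h array or LQ control B, with adjusted p up to 0.468, and with no filter, a stricter filter, the compared groups only or fry (up to 0.277). The markers of other cell types shifted up at 1 h in WT (camera adjusted p = 0.0228, median log2 change 0.58, letter A 0.47, letter B 0.31, 9 measured), and adjusted p = 0.206 with an estimated correlation. Their highest changes were those of CD3E, a T cell receptor component (0.93), and DCN, a proteoglycan of fibroblasts (0.80), and 0 of 9 passed on their own. Both signals were dim and near the filter of 15.5. From WT control to 1 h, CD3E went from 12.7 to 38.3 and DCN from 21.2 to 46.2. The call was lost without WT control B, WT 1 h A or WT 1 h B, with adjusted p up to 0.163, and with no filter, a stricter filter or fry (up to 0.26). The actin 3' to 5' ratio, a sign of RNA quality, was 1.33 ± 0.103 in WT controls and 1.15 ± 0.0822 at 1 h, and that of GAPDH 0.883 ± 0.0278 and 0.757 ± 0.0177 (n = 2 each), with no overlap. WT 1 h A stood apart on the second principal component (33.8, next highest array 21.7).

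After 2 h of E2 in WT cells, 7 probe sets of 7 genes passed, 5 higher and 2 lower. SMOX reached 605 ± 77.2, a 3.58-fold rise (log2 change 1.84, SE 0.19, adjusted p = 0.00129, n = 2 each). OTUB2, a deubiquitinating enzyme, rose 3.03-fold from 301 ± 22.1 to 941 ± 5.42 (adjusted p = 0.00129). SOX9, a transcription factor of cell fate, rose 2.56-fold from 422 ± 34.5 to 1105 ± 3.29 on the brighter of its probe sets (adjusted p = 0.0244). CEBPB, a leucine zipper transcription factor, rose 2.12-fold from 1105 ± 7.45 to 2357 ± 37.7 (adjusted p = 0.00542).

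BHLHE40 stayed 2.07-fold higher at 2 h (adjusted p = 0.0409), and KLF6 was 2.97-fold lower (log2 change -1.57, SE 0.21, adjusted p = 0.00978). MYC, a growth-promoting transcription factor, fell from 762 ± 26.5 to 393 ± 39.9, 1.91-fold lower (log2 change -0.93, SE 0.15, adjusted p = 0.0409). The changes of MXD1, an antagonist of MYC (log2 change 2.08, adjusted p = 0.12), DEPP1 (1.90), TMEM259, TOB1, CSF1, TRAV8-3, CRISPLD2 and CLCN4 did not pass, nor did those of CDC42EP2 (-1.60), JUN (-1.26, adjusted p = 0.0768), GPR107, PIK3R3, CCL2, ZFP36L1, SLAMF7 and ZNF574. TFF1, a classical estrogen-induced gene, had a log2 change of 1.15 (SE 0.26) that did not pass (adjusted p = 0.278).

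With the letter as a block, 29 probe sets passed at 2 h in WT, 18 higher and 11 lower, and all 7 were among them. In the blocked fit 969 had an unadjusted p under 0.05, above the 740 that chance gives. Genes added by the block included TOB1 (log2 change 1.45, adjusted p = 0.303 without the block and 0.00337 with it), RARA, the retinoic acid receptor alpha (1.25), the phosphatases DUSP5 (-0.92) and DUSP6 (-1.09), the chemokines CCL2 (-1.22) and CXCL8 (-1.04), JUN (-1.26) and MXD1 (2.08). Without WT control B or WT 2 h B 0 probe sets passed in limma, against 533 with an unadjusted p under 0.05 on all arrays, below the 740 that chance gives. Without WT 2 h A 1 passed, without WT control A 2 passed, and without either LQ 1 h array 4 passed. BHLHE40 and MYC kept their calls only without either WT 1 h array, with adjusted p up to 0.517 and 0.849 otherwise. CEBPB (up to 0.149) and KLF6 (up to 0.282) lost theirs without any WT control or WT 2 h array, SOX9 (up to 0.388) also without either LQ 1 h array, OTUB2 (up to 0.0675) without WT control B or either WT 2 h array and SMOX without WT control B or WT 2 h B. All 7 calls were lost with a common median (adjusted p up to 0.716). Without an intensity trend SOX9, CEBPB, BHLHE40 and MYC lost theirs, with no filter SOX9 and BHLHE40, and on the deposited scale or with the compared groups only BHLHE40 and MYC.

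**Figure D1:**
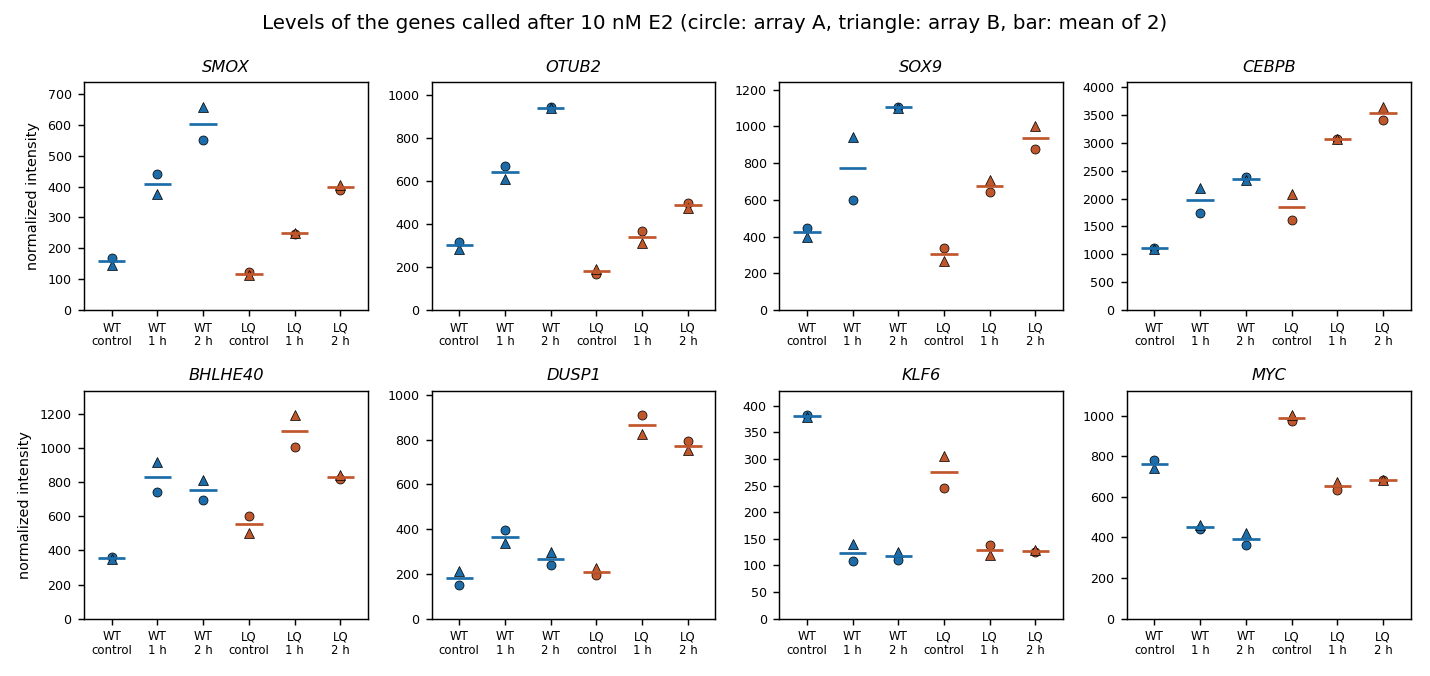
Normalized intensity of SMOX, OTUB2, SOX9, CEBPB, BHLHE40, DUSP1, KLF6 and MYC on each of the 12 arrays, by line and time of E2 (circles, letter A; triangles, letter B; bars, mean of 2 arrays). SMOX went from 157 to 605 in WT and from 118 to 399 in LQ at 2 h, and DUSP1 from 209 to 867 in LQ at 1 h.

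Of the immediate early genes, 2 rose and 12 fell at 2 h in WT, adjusted over the list alone, and 16 did not pass; over all probe sets 2 fell. The list shifted down (camera adjusted p = 0.000186, median log2 change -0.22), and adjusted p = 0.103 with an estimated correlation. Besides KLF6 and MYC, the members that fell included JUN (-0.66 for the list's probe set) and CCN2, a matricellular protein (-0.69). At 2 h in WT the actin ratio was 1.14 ± 0.106 and the GAPDH ratio 0.799 ± 0.0106, against 1.33 ± 0.103 and 0.883 ± 0.0278 in the controls, again with no overlap. Of the MAPK feedback and ETS genes, 1 rose and 5 fell, adjusted over the list alone (camera adjusted p = 0.00794, median log2 change -0.29, letter A -0.37, letter B -0.04), and adjusted p = 0.206 with an estimated correlation. DUSP5 (-0.92), DUSP6 (-0.84) and FOSL1 (-0.51) fell and DUSP7 rose (1.14). Without WT control A this call was lost (adjusted p = 0.0552), as it was with fry (0.192). Of 33 classical estrogen-induced genes, 4 rose and 1 fell, adjusted over the list alone (camera adjusted p = 0.0376, median log2 change 0.16, letter A 0.22, letter B 0.14), and adjusted p = 0.334 with an estimated correlation. RARA (1.25), TFF1 (1.15) and FHL2, a LIM domain cofactor (0.61), were among those that rose, and MYC was the member that fell. This call was lost with the letter as a block (adjusted p = 0.0569) and without WT control B or WT 2 h A, with adjusted p up to 0.261. A stricter filter, the compared groups only and fry ended it too (up to 0.129).

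In LQ cells, 1 probe set passed the threshold after 1 h of E2. DUSP1, a phosphatase that inactivates MAP kinases, rose 3.93-fold from 209 ± 22.2 to 867 ± 57.7 (n = 2 each, log2 change 1.97, SE 0.20, adjusted p = 0.00163). The changes of SOX9 (log2 change 1.33, adjusted p = 0.112), KLF10, a TGF-beta-inducible zinc finger factor (1.35, adjusted p = 0.123), GADD45B, a stress sensor (1.22, adjusted p = 0.123), CHRM4, CSF1, SVIL, NOTCH3 and DHRS9 did not pass. Those of TMEM176A (-1.55), ABCF2, CLSPN, PARD3, RNFT2, GAMT (-1.18), MED14 and PTPN21 did not pass in the other direction. When the letter was a block, 8 probe sets passed, all higher, which added BHLHE40, KLF10, CEBPB (log2 change 0.74) and 2 probe sets each of SOX9 and GADD45B. In the blocked fit 518 had an unadjusted p under 0.05. The DUSP1 call was lost without LQ 1 h A (adjusted p = 0.0793) or with a common median (0.152), which left 0 calls, while 284 probe sets had an unadjusted p under 0.05 on all arrays, below the 740 that chance gives. Without WT 1 h A 3 probe sets passed, and without WT 1 h B 2 passed.

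Of 18 measured TGF-beta targets, 4 rose at 1 h in LQ, adjusted over the list alone, and 14 did not pass. They were KLF10 (log2 change 1.35), BHLHE40 (0.97), SMAD7, the inhibitory SMAD (1.09), and CDKN1A, the cyclin-dependent kinase inhibitor p21 (0.84). At 1 h in WT 4 members rose too and 1 fell, adjusted over the list alone. The list there passed with fry (adjusted p = 0.0358) but not with camera (adjusted p = 0.251). The lines did not differ in the list's E2 effect at 1 h past the threshold (camera adjusted p = 0.526). In LQ at 1 h the list shifted up (camera adjusted p = 0.00126, median log2 change 0.10), and adjusted p = 0.103 with an estimated correlation. This call was lost without LQ 1 h B (adjusted p = 0.0965) and with no filter (0.0562).

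After 2 h of E2 in LQ cells, 6 probe sets of 5 genes passed, all higher. DUSP1 was 3.51-fold higher at 772 ± 28.9 (log2 change 1.81, SE 0.20, adjusted p = 0.00327, n = 2 each). SOX9 rose 3.30-fold from 110 ± 19.5 to 398 ± 6.08 on the dimmer of its probe sets (adjusted p = 0.00402), and the brighter one had a log2 change of 1.59. SMOX rose 3.10-fold from 118 ± 6.44 to 399 ± 11.5 (adjusted p = 0.00327). OTUB2 rose 2.56-fold (adjusted p = 0.00407), and CEBPB rose 1.92-fold from 1843 ± 326 to 3529 ± 172 (adjusted p = 0.0133).

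The changes of CST1, a cystatin (log2 change 1.24, adjusted p = 0.139), CSF1, GPC1, ZMIZ1, IL17RC, HEG1, FOSL2 and AMOTL2 did not pass, nor did those of PCOTH (-1.40), ABCF2, DDX31, PBXIP1, PHF1, TSPAN1, KLF2 (-1.13), CCL2 (-1.13) and KLF6 (-1.02, adjusted p = 0.224). TFF1 had a log2 change of 0.92 (adjusted p = 1), from 13.5 ± 1.64 to 39.7 ± 4.77 in LQ against 83.5 ± 11.1 to 206 ± 39.3 in WT. The LQ control level lay under the filter of 15.5. The pseudocount therefore shrinks the LQ change more, and the log2 changes of TFF1 do not rank the lines. When the letter was a block, 11 probe sets passed, which added FHL2 (0.86), TGFA, a ligand of the EGF receptor (0.84), CST1, ZMIZ1 and DUSP5 (-0.88). In the blocked fit 575 had an unadjusted p under 0.05. Without LQ 2 h A or LQ 2 h B 0 probe sets passed in limma, and 351 had an unadjusted p under 0.05 on all arrays, below the 740 that chance gives. Without LQ control A 3 passed, and the dimmer SOX9 probe set, OTUB2 and CEBPB then lost their calls, with adjusted p up to 0.369 over the arrays left out. Without either WT 1 h array 10 passed. With a common median or the compared groups only 0 passed, with adjusted p up to 0.399 for the 5 genes, and CEBPB was lost with no filter (0.107) or no intensity trend (0.533) as well.

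Of the immediate early genes, 4 rose and 6 fell at 2 h in LQ, adjusted over the list alone, and 20 did not pass. DUSP1 and CCN1 (0.54) rose, and KLF2 (-1.13) and KLF6 (-1.02) fell. The list shifted down (camera adjusted p = 0.0376, median log2 change -0.22), and adjusted p = 0.206 with an estimated correlation. The call was lost without either WT control, either LQ control or LQ 2 h B, with adjusted p up to 0.5. It was also lost on the deposited scale (median -0.08), with a common median (-0.15), a pseudocount of 1, a stricter filter or fry, with adjusted p up to 0.0927.

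Computed within letter A and within letter B, the log2 changes across probe sets had r = 0.08 at 1 h and 0.161 at 2 h in WT, and 0.046 and 0.08 in LQ. In neither line and at neither time did CCND1 or CTSD pass. PGR (mean 5.76) and the 3 GREB1 probe sets (highest mean 11.3) lay under the filter and were not tested.

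The difference between the lines in the E2 effect was tested directly. With limma, 0 probe sets passed at 1 h and 0 at 2 h, while 392 and 291 had an unadjusted p under 0.05, against 740 that chance gives. Blocking on the letter, 0 passed at either time, and 834 and 596 had an unadjusted p under 0.05. For DUSP1 the log2 change in LQ minus that in WT was 1.00 at 1 h (95% interval 0.39 to 1.61, adjusted p = 0.999) and 1.27 at 2 h (0.66 to 1.88, adjusted p = 1), which did not pass. The SMOX difference at 2 h was -0.21 (-0.77 to 0.36) and that of KLF6 0.55 (-0.08 to 1.18), intervals that leave room for differences in either direction. No gene list passed for the difference in the E2 effect, and the smallest adjusted p was 0.0696, for the immediate early genes at 2 h.

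Of the probe sets higher at 2 h, 5 in WT and 6 in LQ, 4 were shared, where independent calls would share 0.00203. Blocking on the letter, 5 were shared of 18 and 10. At 1 h 0 were shared of 2 and 1, and 4 of 6 and 8 with the block. Across all 14810 probe sets, which are not independent, the log2 changes of both lines had r = 0.066 and rho = 0.041 at 1 h (exact permutation p = 0.889) and r = 0.097 and rho = 0.054 at 2 h (exact permutation p = 0.444, two-sided). The adjusted p was 0.889 for both, and the smallest p the design allows is 0.111. The 36 namings include those that set both A arrays against both B arrays, and these carry the letter difference that the lines share. The permutation p-values therefore do not decide whether the lines share an E2 response. Within a line, the changes at 1 and 2 h share their controls. Their r was 0.565 in WT and 0.508 in LQ, where simulated data without any effect gave 0.5 and 0.501.

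**Figure D2:**
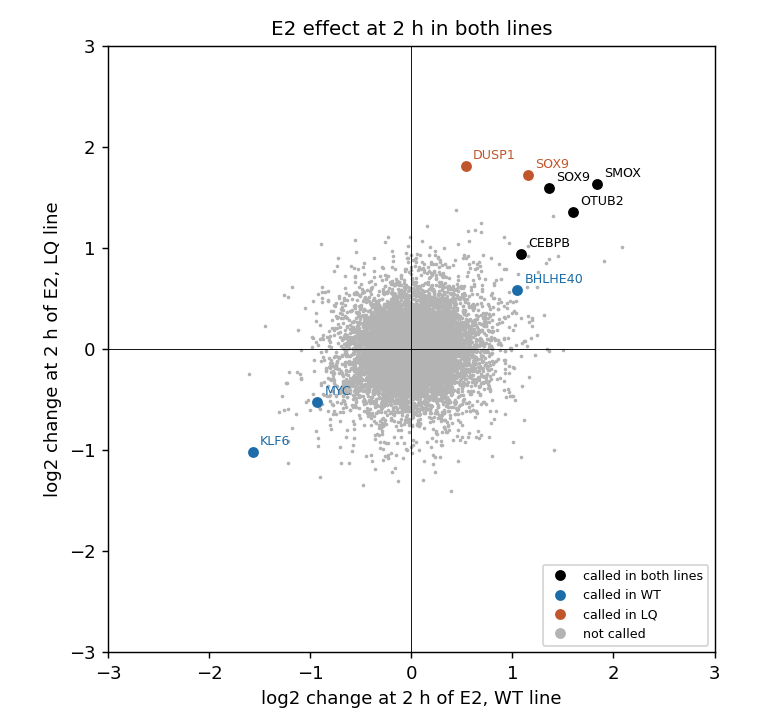
Log2 change after 2 h of E2 in WT (horizontal) and LQ (vertical) for 14810 probe sets. Probe sets past an adjusted p of 0.05 are black if called in both lines (4), blue if in WT and orange if in LQ.

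Between the controls, 177 probe sets differed between the lines, 88 higher and 89 lower in LQ, of which 132 differed more than 2-fold. CSTA, which encodes the protease inhibitor cystatin A, was 14.2-fold higher in LQ, at 278 ± 3.96 against 4.77 ± 1.13 (n = 2 each, log2 difference 3.83, SE 0.25, adjusted p = 1.15e-06). HCLS1, a hematopoietic adaptor protein, was 9.68-fold higher at 412 ± 45.5 against 28.1 ± 2.16. SH3BGRL, a small SH3-binding protein, was 18.9-fold lower in LQ, at 3.26 ± 3.27 against 346 ± 14.1. OASL, an interferon-induced protein, was 7.67-fold lower and IFIT3, another of that class, 6.33-fold lower at 159 ± 15 against 1093 ± 19.3. Folds against levels this close to 0 depend on the pseudocount. With a pseudocount of 1 the log2 difference was 5.61 for CSTA and -6.60 for SH3BGRL, and with 64 it was 2.32 and -2.61.

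Further genes higher in LQ controls were VEGFA, an angiogenic growth factor (log2 difference 2.25), THBD, MMP14, PLEC, PXN, TIE1, HMGA1, TMEM259, DDIT4 and ABCF2. Further genes lower in LQ were CST1, CES1, CST4, IFIT2, MMP1, the interstitial collagenase (-2.66), IFIT1, IFI44, ASB9 and TERT. TFF1 was lower in LQ as well (log2 difference -1.75, adjusted p = 0.00265), a call lost without WT control B (adjusted p = 0.0572). The calls of PLEC, HMGA1, ABCF2 and TMEM259 were lost without WT control A or LQ control A, that of TMEM259 also without LQ control B, and that of MMP14 without either WT control. With another pseudocount the sizes of VEGFA, PLEC, MMP14, PXN, TIE1, HMGA1, TMEM259, ASB9, TERT and TFF1 moved by over 1.5 times. TIE1, DDIT4 and PXN lost theirs without any of the 4 control arrays, PXN also without either LQ 1 h array, with adjusted p up to 0.342. With no filter PXN, TMEM259 and DDIT4 lost their calls, and with no intensity trend PXN and TMEM259 (up to 0.129). Blocking on the letter, 501 probe sets passed, 277 higher and 224 lower. The count was 112 with a common median, 103 with no intensity trend, 54 without WT control A, 61 without WT control B, 58 without LQ control A, 92 without LQ control B, 296 without WT 1 h A and 298 without WT 1 h B.

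Of 20 measured genes of cholesterol and fatty acid synthesis, 7 were higher in LQ controls and 0 lower, adjusted over the list alone. INSIG1, a regulator of sterol sensing (log2 difference 1.54), SQLE, squalene epoxidase (1.25), HMGCS1 (1.10) and MSMO1 (1.02) were among them (camera adjusted p = 4.02e-10, median 0.53), and adjusted p = 0.0205 with an estimated correlation. Of 31 interferon response genes 11 were lower and 1 higher (camera adjusted p = 1.05e-06, median -0.14, mean -0.59), and adjusted p = 0.103 with an estimated correlation. IFIT2 (-2.68), IFI44 (-2.62) and ISG15 (-1.53) were among those lower. Of 24 hypoxia and glycolysis genes 5 were higher and 0 lower (camera adjusted p = 0.0007, median letter A 0.29, letter B 0.16), and adjusted p = 0.103 with an estimated correlation, with VEGFA at 1.27 for the list's probe set and NDRG1 at 0.86.

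Other lists also passed between the control arrays. Among these arrays the actin 3' to 5' ratio was 1.05 ± 0.134 in LQ and 1.33 ± 0.103 in WT, and the GAPDH ratio 0.786 ± 0.0393 and 0.883 ± 0.0278 (n = 2 each), with no overlap in either. Of 24 NF-kB targets and cytokines 6 were lower in LQ, among them CCL2 (-2.29), CXCL8 (-2.32) and IL7R (-2.39); the camera adjusted p was 0.0376 (median -0.16, letter A -0.29, letter B -0.11), and adjusted p = 0.264 with an estimated correlation. That call was lost with the letter as a block (adjusted p = 0.0727) and without WT control A, WT 1 h A, WT 1 h B or LQ control B, with adjusted p up to 0.171, and with a common median, no filter, a stricter filter or the compared groups only (up to 0.107). Of 18 TGF-beta targets 3 were lower and 1 higher, with TGFBI at -1.89 and SMAD6 at -1.71 (camera adjusted p = 0.0228), and adjusted p = 0.206 with an estimated correlation. This call was lost without WT control B (adjusted p = 0.0756) and with no filter (0.0562). Of 30 immediate early genes 2 were higher and 2 lower (camera adjusted p = 0.0376, median 0.22, letter A 0.28, letter B 0.10), and adjusted p = 0.206 with an estimated correlation. It was lost without WT control A, LQ control A or LQ control B, with adjusted p up to 0.173, and on the deposited scale, with a common median or the compared groups only (up to 0.18).

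Of 23 genes of unfolded protein and amino acid stress 4 were higher, among them DDIT4 (1.69), CEBPB (0.72) and ATF4 (0.69) (camera adjusted p = 0.0376, median 0.07, letter A 0.06, letter B 0.16), and adjusted p = 0.206 with an estimated correlation. It was lost without either WT control, either WT 1 h array or LQ control B, with adjusted p up to 0.187. The deposited scale, a common median, a pseudocount of 1, no filter, a stricter filter and the compared groups only each ended it as well (up to 0.0913). Of 14 heat shock genes 3 were higher, among them HSP90AB1 (0.62) (camera adjusted p = 0.0376), and adjusted p = 0.206 with an estimated correlation. It was lost with the letter as a block (adjusted p = 0.0569) and without either WT control, WT 2 h A, either LQ control or LQ 1 h B, with adjusted p up to 0.116, and on the deposited scale, with a common median or the compared groups only (up to 0.213).

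Averaged over control, 1 h and 2 h, with 6 arrays for each line, 1807 probe sets differed, 867 higher and 940 lower in LQ, of which 171 differed more than 2-fold. CSTA was 11.2-fold higher in LQ (log2 difference 3.48, SE 0.14, adjusted p = 2.37e-09), HCLS1 9.57-fold and INSIG1 3.38-fold higher. SH3BGRL was 18.4-fold lower (log2 difference -4.20, SE 0.16, adjusted p = 1.06e-09), OASL 9.06-fold, CES1, a carboxylesterase, 7.57-fold, MMP1 6.85-fold and IFIT3 5.82-fold lower. VEGFA, MAGEB2, MMP14, DDIT4, THBD, SBF1, TIE1, MBNL2 and GEM were also higher, and CST1, IFIT2, ISG20, IFI44, IFIT1, CST4 and C3, the complement component (log2 difference -2.45), also lower. TFF1 was lower by a log2 difference of -1.94 (adjusted p = 1.37e-06) and MYC higher by 0.55 (adjusted p = 0.000919).

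The 6 LQ arrays of SH3BGRL read 0.642 to 5.57, and 5 of 6 WT arrays of CSTA lay under the filter of 15.5, so the pseudocount sets these folds. With a pseudocount of 1 the log2 differences were -6.87 and 4.93, and with 64 they were -2.52 and 2.13. Those of VEGFA, MAGEB2, MMP14, DDIT4, SBF1, TIE1, ISG20, C3 and TFF1 moved by over 1.5 times too. None of the genes in this and the preceding paragraph lost its call when any single array was left out, and MYC lost its call with a common median (adjusted p = 0.0582). Blocking on the letter, 2929 probe sets passed, 1411 higher and 1518 lower. When each array was shifted to a common median in place of quantile normalization, 1162 passed, 393 higher and 769 lower, so the share of higher calls was 33.8% against 48.0%. The count was 1160 without WT control B and 1176 without WT control A.

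**Figure D3:**
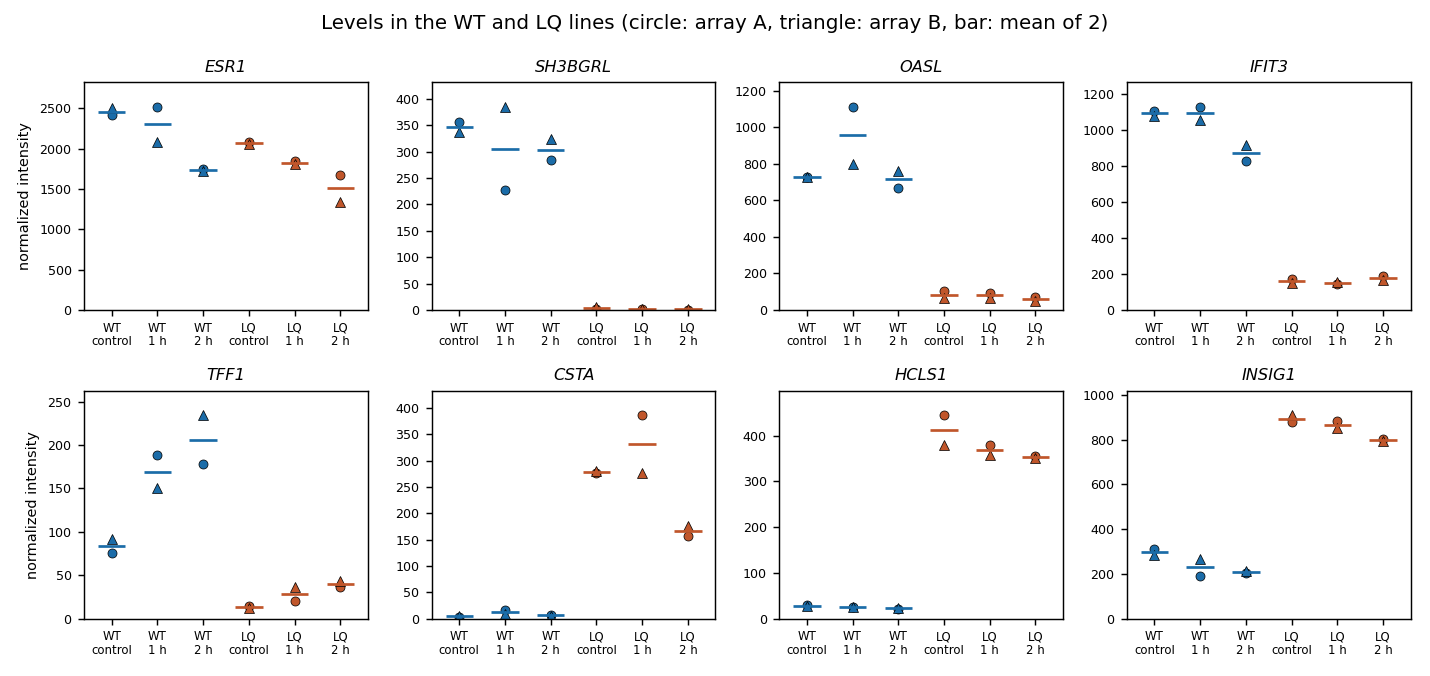
Normalized intensity of ESR1, SH3BGRL, OASL, IFIT3, TFF1, CSTA, HCLS1 and INSIG1 on each of the 12 arrays, by line and time (circles, letter A; triangles, letter B; bars, mean of 2 arrays). IFIT3 read 1093 in WT controls and 159 in LQ controls.

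Over all times, 13 of 20 cholesterol and fatty acid synthesis genes were higher in LQ and 0 lower, adjusted over the list alone (11 over all probe sets; camera adjusted p = 2.19e-10, median 0.46), and adjusted p = 0.0205 with an estimated correlation. Of 31 interferon response genes 14 were lower and 2 higher (camera adjusted p = 2.62e-07, median -0.31), and adjusted p = 0.103 with an estimated correlation. Of 24 hypoxia and glycolysis genes 7 were higher and 1 lower (camera adjusted p = 0.0119), and adjusted p = 0.16 with an estimated correlation. The one lower was PFKFB3 (-0.64), a regulator of glycolysis. Of 30 immediate early genes 12 were higher and 4 lower, with GEM at 1.37 and DUSP1 at 0.96 (camera adjusted p = 0.00794, median letter A 0.24, letter B 0.15), and adjusted p = 0.131 with an estimated correlation. Of 14 heat shock genes 4 were higher, with HSPD1 at 0.35 (camera adjusted p = 0.0331, median 0.16), and adjusted p = 0.206 with an estimated correlation. The heat shock call was lost on the deposited scale (median 0.14, adjusted p = 0.116) and with a common median (0.06, adjusted p = 0.18).

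Of 19 MAPK feedback and ETS genes 9 were higher and 2 lower over all times, with IER3 at 0.60 and SPRY2 at -0.67 (camera adjusted p = 0.0376, median letter A 0.29, letter B 0.13), and adjusted p = 0.334 with an estimated correlation. This call was lost without WT control A, WT 1 h A, WT 2 h A, LQ control B or LQ 2 h B, with adjusted p up to 0.0997, and on the deposited scale, with a common median, a stricter filter or fry (up to 0.167). Of 18 TGF-beta targets 2 were higher and 6 lower, with TGFBI at -1.64 and THBS1 at -0.53 (camera adjusted p = 0.0376), and adjusted p = 0.206 with an estimated correlation. The actin ratio over all times was 1.07 ± 0.111 in LQ and 1.21 ± 0.121 in WT, and the GAPDH ratio 0.784 ± 0.0585 and 0.813 ± 0.0596 (n = 6 each). The TGF-beta call was lost without WT control B, WT 1 h A, WT 1 h B or LQ 2 h B, with adjusted p up to 0.0917, and with a stricter filter (0.118).

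**Figure D4:**
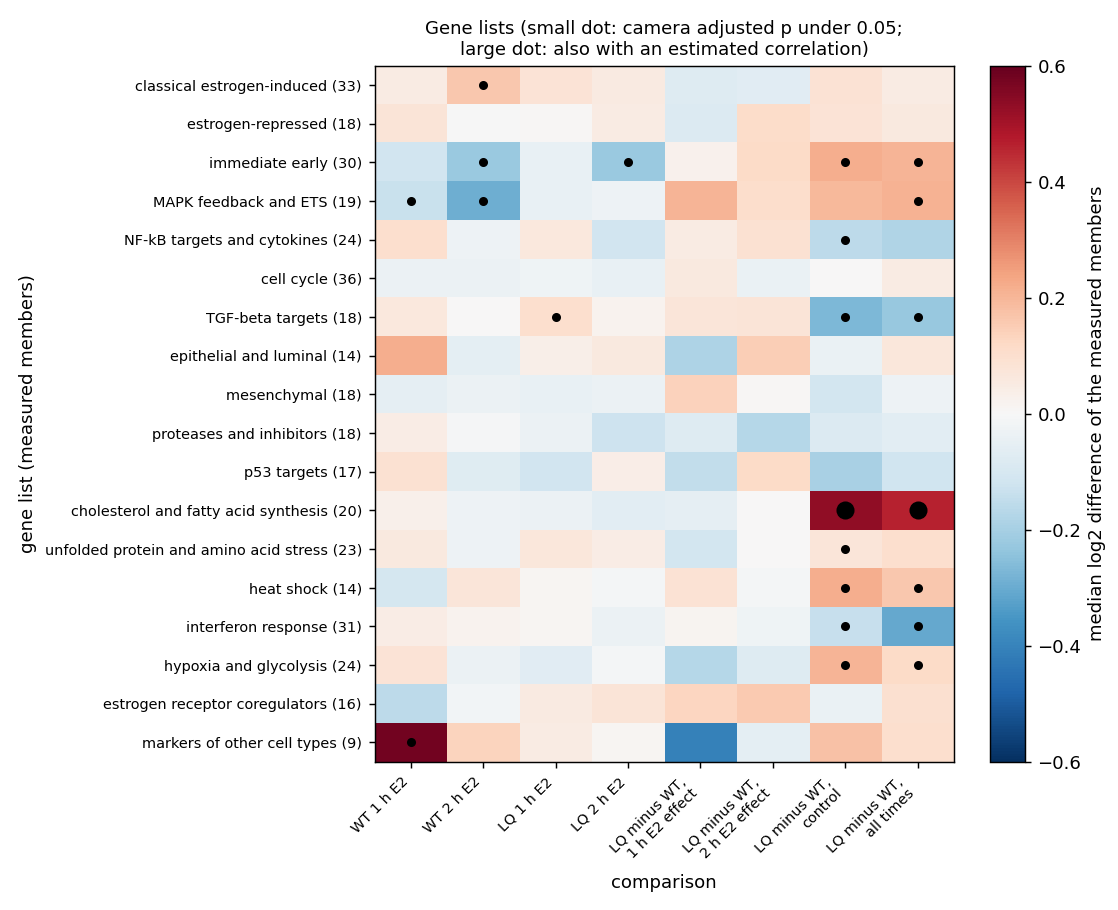
Median log2 difference of each of the 18 gene lists in each comparison (color), with a small dot where camera's adjusted p was under 0.05 and a large dot where it was also under 0.05 with an estimated correlation. Large dots stand only at cholesterol and fatty acid synthesis in the comparisons of the lines.

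The other 7 lists passed in none of the 8 contrasts. Their smallest camera adjusted p was 0.17 for estrogen receptor coregulators, 0.29 for epithelial and luminal genes, 0.303 for mesenchymal genes, 0.35 for cell cycle, 0.382 for estrogen-repressed genes and for p53 targets, and 0.515 for proteases and inhibitors. Single members still differed between the lines over all times. TGFBR2, a TGF-beta receptor of the mesenchymal list, was lower in LQ (log2 difference -0.73, adjusted p = 0.000673), CENPE of the cell cycle list higher (1.17, adjusted p = 0.00613), CYP1A1 of the estrogen-repressed list lower (-0.90, adjusted p = 0.00159) and EP300, a coactivator, higher (0.64, adjusted p = 0.0243). TP53I3, a p53 target, was lower (-0.47, adjusted p = 0.0262), and TIMP1, a metalloproteinase inhibitor, was lower (-0.50, adjusted p = 0.00139).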

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

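The list of genes looked at here, 69 named probe sets at both times, was drawn by a rule set beforehand, and the tests of the actin and GAPDH ratios as covariates, given with the other observations, were chosen after the result was seen. The 5 results below stand out because every E2 array of one line lay on the opposite side of its control from every array of the other line. All 5 genes had been named for the size of a change after E2 in these same data. With 2 arrays on each side, such an opposite order can arise by chance among 69 probe sets. No chance rate was computed. In each case the interaction was tested and did not pass in limma (adjusted p = 0.999 at 1 h and 1 at 2 h). IGLL5, at 1 h, had a log2 change of 1.46 in WT and -0.41 in LQ, a difference of -1.87. GPR107, at 1 h, had -1.01 in WT and 0.60 in LQ, a difference of 1.62. NOTCH3, at 1 h, had -0.59 in WT and 1.18 in LQ, a difference of 1.77. GAMT, at 1 h, had 0.28 in WT and -1.18 in LQ, a difference of -1.46. SLAMF7, at 2 h, had -1.18 in WT and 0.62 in LQ, a difference of 1.79. No explanation was weighed for these genes.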

How the results depend on the processing

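Tests added after the data were seen were the fits on the arrays of 1 letter, the fits without both WT 1 h arrays and the E2 effect averaged over lines and times. Shifting each array to a common median left 0 calls for E2 at 1 and 2 h in WT and in LQ, 112 between control lines and 1162 over all times. On the deposited scale the ESR1 difference was -0.30 (adjusted p = 0.082). Without a filter 0 probe sets passed at 1 h in WT and ESR1 stood at -0.26 (adjusted p = 0.0634), and with the stricter filter 14 list tests passed against 22. Without an intensity trend the counts were 0 at 1 h and 3 at 2 h in WT and 103 between controls, and the adjusted p of ESR1 (-0.26) was 0.154. The letter as a block gave 8 and 29 in WT, 8 and 11 in LQ, 501 between controls and 2929 over all times. Fits on the compared groups alone, which have fewer arrays, gave 0 at 1 h in WT and 0 at 2 h in LQ. With 1 probe set per gene, so fewer tests, 5 passed at 1 h in WT and 1192 over all times. At a threshold of 0.10 the counts were 6 at 1 h in WT and 310 between controls. With an estimated correlation 2 list tests passed. Letter A alone gave 512 calls over all times and letter B alone 2460, and without both WT 1 h arrays 2 passed at 1 h and 10 at 2 h in LQ. The averaged E2 effect gave 27 without the block. Leaving out 1 array at a time, the counts ran from 0 to 295 and 0 to 8 in WT, 0 to 3 and 0 to 10 in LQ, 0 to 0 for both interactions, 54 to 298 between controls, 1160 to 2521 over all times, 14 to 24 list tests and 20 to 66 for averaged E2. ESR1 ran from -0.31 to -0.21. The correlation of the lines ran from -0.144 to 0.264 at 1 h, also reversed without LQ 1 h A (-0.088), and from -0.073 to 0.25 at 2 h, also reversed without LQ control B (-0.071). Except where fewer arrays or tests account for it, the cause was not tested. Of 16 named E2 calls 0 held under every alternative set beforehand with all arrays and 0 under every left-out array, and of 52 named line calls 47 and 42 did; none reversed. The blocked fit ended no call of a named gene. Signals near the filter limit folds of dim genes.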

Other observations

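The comparison in the next paragraphs, E2 averaged over lines and times, the tests of the actin and GAPDH ratios and the test of one letter's calls on the other letter's arrays were chosen after the result was seen. Averaged over both lines and both times, with line and letter in the fit, 41 probe sets differed between the 8 E2 arrays and the 4 control arrays, 30 higher and 11 lower. Without the letter 27 passed, 22 higher and 5 lower. With arrays shifted to a common median 43 passed, 21 higher and 22 lower, so the mostly higher balance depends on the scaling. Among the 41, SNAI2, a transcription factor of epithelial-mesenchymal transition, rose (log2 change 0.72, adjusted p = 0.000585). Genes already named above rose too. They included CDKN1A, the kinase inhibitor p21 (0.79, adjusted p = 0.00133), AMOTL2 (0.93) and FOSL2, an AP-1 subunit (0.92). SMAD7 (0.89), CSF1, a macrophage growth factor (1.27), and CCN1 (0.53) were also among them. TFF1 rose by 0.88 (adjusted p = 0.0119) and RARA by 0.79. CEBPB rose 1.86-fold (0.90, SE 0.08, adjusted p = 5.52e-05) and KLF6 was 2.43-fold lower (-1.28). MYC (-0.69), JUN (-0.87), DUSP6 (-0.68), TRIB1 (-0.71), FOXA2 (-0.61), ADM (-0.59) and JAG1 (-0.48) also fell. The calls of RARA, DUSP6, FOXA2, ADM and JAG1 exist only with the letter in the fit (adjusted p without it 0.0838, 0.109, 0.167, 0.0814 and 0.303).

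Of 30 immediate early genes 7 rose and 13 fell with E2 averaged, adjusted over the list alone (camera adjusted p = 0.024, shifted down), and adjusted p = 0.317 with an estimated correlation. Of 19 MAPK feedback and ETS genes 2 rose and 6 fell (camera adjusted p = 0.0272), and adjusted p = 0.317 with an estimated correlation. Of 24 NF-kB targets and cytokines 2 rose and 5 fell (camera adjusted p = 0.93, median 0.03). The classical estrogen-induced list did not pass with E2 averaged (camera adjusted p = 0.145), and 3 of its 33 genes rose and 2 fell. Nor did the TGF-beta targets pass (camera adjusted p = 0.115), with 4 of 18 higher and 1 lower. Both lists had an adjusted p of 0.317 with an estimated correlation. Of 9 markers of other cell types 3 rose, DCN, CD3E and HBB (camera adjusted p = 0.105), and adjusted p = 0.317 with an estimated correlation. Without either WT control array 20 probe sets passed, without LQ control B 22, without WT 2 h B 26 and without WT 1 h A 66. In WT the GAPDH 3' to 5' ratio was 0.778 ± 0.0273 on the 4 E2 arrays and 0.883 ± 0.0278 on the 2 controls, and that of actin 1.15 ± 0.0773 and 1.33 ± 0.103, with no overlap; in LQ they overlapped (0.782 and 0.786, 1.08 and 1.05).

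The averaged E2 effect may be biological or technical, and handling apart from E2 cannot be told apart from E2, since 0 arrays of cells without either receptor were analysed here. Of 100 relabellings of E2 and control within the lines, the real one with 41 calls included, 2 gave as many. The highest other, with 49, made 4 letter A arrays the controls, and the 3 others of that kind gave at most 1. The comparison was chosen after the result was seen, and other relabellings leave any real effect in the residual, which lowers their counts. Chance is therefore not excluded. All 27 calls made without the letter (100%) were kept with it, but every group holds both letters, so a letter term cannot move the estimates and this test decides nothing. For RNA integrity, the criterion set before was the share of calls kept with the actin 3' to 5' ratio as a covariate; 51.2% were kept, between its bounds, and 46.3% with the GAPDH ratio, which by the same bounds would count for that explanation. By a criterion chosen after the actin result, the median log2 difference was 1.03 times its size with the actin ratio (10th to 90th percentile 0.88 to 1.10) and 0.977 times with the GAPDH ratio (0.892 to 1.07), while the median SE went from 0.121 to 0.132 and 0.136, which argues against RNA integrity as the whole cause only as far as a criterion chosen with a result in view can.

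The difference between the lines may stem from the receptor or from other differences between isolated lines, which cannot be told apart, since the labels name 1 line per receptor. Of 100 splits of the 12 arrays into 6 and 6, only the real 1 gave as many calls (2112 with line and time in the fit, highest other 332). Other splits leave the line difference in the residual, which lowers their counts. The count shows that these arrays group by line. It does not exclude chance differences between cultures, since A and B may be technical. The shifts of the interferon and cholesterol lists were alike on both letters (lower ratio of smaller to larger 0.907), but these lists had the strongest shifts, and the MAPK list had 0.29 and 0.13, so this decides nothing. Of 533 probe sets called on the letter A arrays alone, normalized with all 12, 96.4% had the same sign on letter B with a median 0.713 times as large (10th percentile 0.291), and of 2407 called on letter B 94.7% on letter A, 0.897 times as large (0.207), which argues against a difference on 1 letter only. With the actin ratio, which was 1.07 ± 0.111 in LQ and 1.21 ± 0.121 in WT (exact permutation p = 0.0628, n = 6 each), 69.5% of the calls were kept, again between the bounds of the criterion set before; by the one chosen afterwards the median log2 difference was 1.00 times its size (0.692 to 1.30), with a median SE of 0.142 against 0.125, and the same limit applies.

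The markers of other cell types, higher at 1 h in WT, may reflect RNA of other cells or the array WT 1 h A, which stood apart in the principal components. Their median lay at percentile 99.99 of 10000 random lists of matched level on both letters together. On letter B alone it lay at 98.44, under the bound of 99 set beforehand. The list was looked at because it had passed in this same contrast, and the random lists drew each gene independently. The percentiles show a larger rise than in most lists of similar level. They do not decide against a general rise of dim probe sets, which stays open. On the letter B arrays alone the median was 0.31, above the bound of 0.29 set beforehand. It exceeded that bound by less than 0.136, the SD of the medians of random lists of matched level on letter B. This was first read as excluding WT 1 h A and was changed to undecided after the value was seen, so that array stays open. The 3 brightest members, PECAM1 (162 to 177), COL1A1 and HBB, had a median of 0.29, so RNA of other cells stays open too, although ACTA2 (-0.10) and COL1A2 (-0.27) were lower. No biological explanation was tested.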
